A study of Homo sapiens with 6 samples.

How the data were processed

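RNA was measured by sequencing in 6 libraries of K562 cells, 3 with wild-type RUNX1 (WT) and 3 with RUNX1 R320*. Per the labels, the cells grew in RPMI-1640 with 10% FBS, total RNA was extracted with TRIzol, and libraries were made with a NEBNext Ultra II RNA kit. Per the submitters' processing notes, HISAT2, featureCounts, DESeq2 and Salmon were used with the hg38 genome build. Their versions, parameters and the tool behind each table are not given in the sources used here, nor are poly(A) selection, the use of strand in counting, how the R320* change was made, or whether the replicates are separate cultures.

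The deposited signal values were normalized read counts for 28395 Entrez genes in the 6 libraries, which the authors had divided by 1 factor per library. The values in each library were whole multiples of its smallest value (100% of values within 1e-06), so reads could be recovered, and 1 read stood for between 0.953 and 1.05 normalized counts. No read was seen in any library for 8336 genes. RefSeq annotation of GRCh38.p14 gave a symbol and position for 27745 identifiers, and the 650 others, with 0.0834% of reads, carried no symbol. The deposited RPKM values, made by the authors as the table's title gives them, covered 60131 Ensembl genes, of which 28825 were 0 in all libraries. RPKM columns summed to between 721735 and 786389, so a transcripts-per-million scale with genes left out is not excluded for the deposited values, and an exact 0 there may be a failed estimate.

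Reads assigned to genes came to 29058471, 30595857 and 30044565 in WT and 30705499, 30064538 and 31306435 in R320*. Replicates of a genotype differed by more than counting error, with a chi-square per gene of 5.22 to 8.66 between pairs of libraries, and the common biological coefficient of variation from edgeR was 6.88%.

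The comparison was R320* against WT with 3 libraries each. The log2(normalized count + 1) of 14299 genes with at least 10 normalized counts in at least 3 libraries was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. In the RPKM table, log2(RPKM + 0.1) of 17769 genes with at least 0.5 in at least 3 libraries was fitted in the same way. A fold change against a genotype with no read in any library was given as a bound against 3 reads in 1 library. Genes seen on 1 side only had a value below 1 in each library of a genotype and of at least 20 in each library of the other.

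There were 35 gene lists on blood lineages, RUNX1, cell processes, RNA quality and other cell types. Those with at least 5 tested members were tested with camera (limma) on the same fit with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, and each p was adjusted over the 31 lists tested. The genes named were RUNX1, RUNX2, RUNX3 and CBFB, and the 12 largest changes in each direction with an adjusted p below 0.05, a mean of at least 50 in the higher genotype, no overlap between genotypes and no clone or pseudogene name. They also took in up to 4 members per list with the smallest adjusted p, the 6 smallest p not yet named, and 3 genes per shifted segment. Some genes that the rule takes in are not reported here. Tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

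Positions were tested on 14141 genes by shuffling log2 fold changes over them 100000 times, with medians per chromosome and per window of 50 neighbouring genes adjusted by the Benjamini-Hochberg method, in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9. Coordinates are GRCh38.

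Methods were tested on simulated data with 3 libraries per group. Of 50 genes changed at each size among 14299, limma recovered 15 at 1.25-fold, 39 at 1.5-fold, 37 at 2-fold and 49 at 4-fold, and called 12 unchanged genes. In simulated RPKM values it recovered 4, 12, 28 and 37, and called 3 unchanged genes. Camera recovered 5 of 5 changed lists with either correlation and called 1 unchanged list with the preset correlation and 0 with the estimated one. The position test found 390 of 400 shifted genes and no segment without a shift. Simulated genes were drawn independently of each other, and far fewer were changed than were called in the data. These rates therefore need not hold for the real libraries, and the simulation does not decide between the 2 camera correlations.

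Alternatives were other pseudocounts, filters, scalings (TMM, quantile, upper quartile), variance models, the replicate number as a block, each library left out in turn, the RPKM table, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on the recovered reads. Fits without the genes of the shifted segments, or with the segment medians subtracted, were added after the data were seen. Alleles, transcript isoforms and raw reads were not analysed here.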

Results

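RNA-seq libraries of K562 cells were compared between 2 RUNX1 genotypes. K562 is an established human leukaemia cell line with erythroid and megakaryocytic features, and RUNX1 encodes a transcription factor of blood cell development. There were 3 libraries of cells with wild-type RUNX1 (WT) and 3 of cells with RUNX1 R320*, a premature stop codon in the C-terminal part of the protein. The WT libraries held 29058471, 30595857 and 30044565 reads assigned to genes, and the R320* libraries held 30705499, 30064538 and 31306435. At least 1 read was seen for between 17096 and 17419 genes per library. The series was set up to find the transcripts that differ between the genotypes, and its title places such C-terminal changes in the context of blocked differentiation and of contacts between enhancers and promoters. Levels below are normalized read counts, given as mean ± SD with n = 3 libraries per genotype. Log2 fold changes are R320* minus WT on the log2(normalized count + 1) scale, with their standard error (SE).

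RUNX1 transcript, from the gene carrying the premature stop, was more abundant in R320* cells. RUNX1 (Entrez gene 861, chromosome 21, 34787801 to 35049302, GRCh38) rose from 2933 ± 31.6 in WT to 5165 ± 124 in R320*, a 1.76-fold difference. Its per-library counts were 2969, 2922 and 2908 in WT and 5209, 5026 and 5261 in R320*. The log2 fold change was 0.82 (SE 0.04, limma adjusted p = 4.4e-11). RUNX1 rose from 22.7 ± 1.78 to 52.5 ± 1.86 in the authors' deposited RPKM table (log2 fold change 1.21, limma adjusted p = 5.53e-05). These gene totals do not separate the 2 alleles or the transcript isoforms, and a nonsense change need not lower a transcript, so they do not test the labels.

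Other members of the RUNX and core-binding factor group also moved. RUNX3 rose from 115 ± 10.8 to 214 ± 3.55 (log2 fold change 0.90, limma adjusted p = 9.56e-05). CBFB, the partner subunit of the RUNX proteins, fell from 3141 ± 177 to 2756 ± 112 (log2 fold change -0.19, limma adjusted p = 0.00487). CBFA2T3, a corepressor related to RUNX1T1, fell from 6052 ± 77.9 to 3705 ± 57.9, while TLE2, a Groucho-type corepressor, rose from 359 ± 35.5 to 752 ± 29.3. RUNX2 was 46.2 ± 4.73 in WT and 82.6 ± 26.0 in R320* (log2 fold change 0.78, SE 0.27, limma adjusted p = 0.0208). Of the 9 tested members 6 were higher and 2 lower, and the list was not called by camera (adjusted p = 0.154). RUNX2 lost its call without WT replicate 2 (limma adjusted p = 0.0617) and without R320* replicate 2 (limma adjusted p = 0.123), within a range of 0.00626 to 0.123 over its alternatives, and its span overlaps that of SUPT3H. CBFB lost its call without the intensity trend (limma adjusted p = 0.0549) and in the RPKM table (limma adjusted p = 0.134), within a range of 0.00193 to 0.134.

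**Figure D1:**
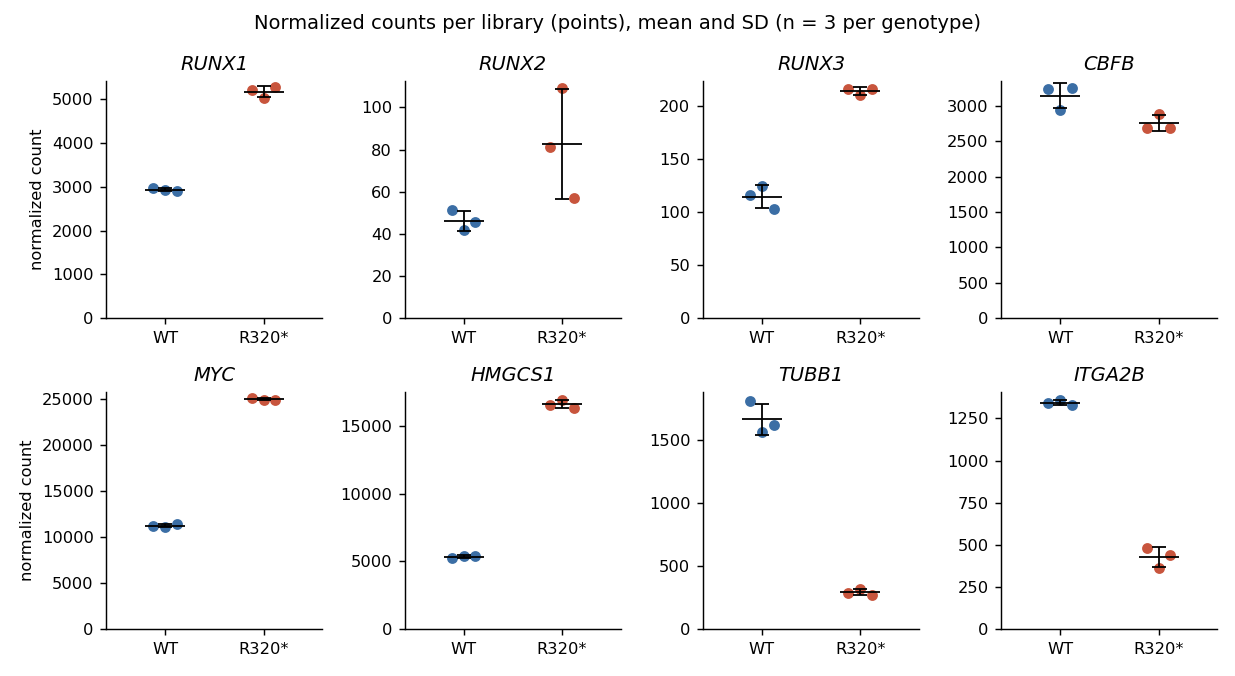
Normalized read counts of 8 genes in each of the 6 libraries (points), with the mean and SD of the 3 libraries per genotype, on axes that start at 0. RUNX1 lay between 2908 and 2969 in the WT libraries and between 5026 and 5261 in the R320* libraries.

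Changes between the genotypes reached 7685 of the 14299 genes tested (53.7%), with 3771 higher and 3914 lower in R320* cells (limma adjusted p below 0.05). Most were small. The median absolute log2 fold change of the called genes was 0.44, and 4784 of them (62.3%) differed by less than 1.5-fold. An absolute log2 fold change of at least 1 was reached by 1626 called genes, 630 of them higher and 996 lower. The 3 WT and 3 R320* libraries did not overlap for 8549 genes (59.8%, against 10% given by chance). Libraries of a genotype were close to each other, with Pearson correlations across genes of 0.988 to 0.989 within a genotype and 0.943 to 0.946 between genotypes. The first principal component held 79.7% of the variance and separated the genotypes, and the second held 5.64%. The labels name no separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

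Among the genes highest in R320* relative to WT were a germline antigen, a secreted growth factor and an actin-bundling protein. MAGEB16, of the melanoma antigen family, had no read in any WT library and 621 ± 94.4 in R320*, at least 208-fold higher against a floor of 3 reads in 1 library. CFAP47, a ciliary gene beside it on chromosome X, rose from 0 to 100.02 ± 28.8 (at least 33.5-fold), and SH2D4A rose from 0 to 62.7 ± 19.7 (at least 20.99-fold). PTN, encoding the growth factor pleiotrophin, rose from 12.9 ± 4.41 to 907 ± 51.1 (log2 fold change 6.08). PLS3, an actin-bundling plastin, rose from 25.04 ± 19.0 to 1132 ± 58.3 (log2 fold change 5.85), DAB2IP, a Ras GTPase-activating protein, from 6.54 ± 7.45 to 500.0 ± 14.7, and SH3D19 from 4.38 ± 2.06 to 554 ± 40.6. FSTL5 rose from 3.37 ± 1.11 to 619 ± 92.3 and MUC19 from 3.39 ± 3.07 to 191 ± 18.0. HAS1, a hyaluronan synthase, rose from 2.71 ± 1.16 to 235 ± 16.4, with a span that overlaps SPACA6. SYT6 was 0.349 ± 0.604 in WT and 122 ± 8.28 in R320*, and ZNF649 was 0.665 ± 1.15 and 103 ± 16.7. All of these had limma adjusted p of at most 1.96e-07.

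Genes with the largest falls included immune receptors, a proteoglycan and utrophin. UTRN, which links the actin cytoskeleton to the membrane, fell from 1081 ± 119 to 3.26 ± 2.27 (log2 fold change -8.11). SRGN, the core protein of the serglycin proteoglycan of blood cell granules, fell from 810.4 ± 58.8 to 5.24 ± 3.07 (log2 fold change -7.17). KYNU, an enzyme of tryptophan breakdown, fell from 389 ± 35.3 to 1.98 ± 3.44, and IL18RAP, a subunit of the interleukin-18 receptor, from 283 ± 12.4 to 1.27 ± 2.20. TREML2 fell from 224 ± 22.5 to 1.32 ± 2.29, MAGED1 from 219 ± 34.8 to 2.58 ± 2.23 and POF1B from 468 ± 19.2 to 9.21 ± 7.97. RFPL4B went from 213 ± 20.1 to 0 in every R320* library (at least 71.3-fold lower), ZNF626 from 156 ± 17.7 to 0 (at least 52.1-fold lower), and RIPOR2 from 76.9 ± 18.0 to 0 (at least 25.7-fold lower). TSPAN32 fell from 1189 ± 56.2 to 17.1 ± 11.5 and C11orf21 from 725 ± 45.7 to 1.92 ± 1.91. The spans of TSPAN32 and C11orf21 overlap, so how their reads divide is uncertain. These 12 genes had limma adjusted p of at most 1.03e-06, and of the 24 largest changes named here 22 were tested in the RPKM table, where all 22 moved in the same direction and were called. Fitted folds were smaller there: of 18 with reads in both genotypes, 13 had a fold over 1.5 times smaller in RPKM. The 0.1 added to each RPKM by itself shrinks folds of genes near 0, so this count does not measure smaller changes alone. UTRN, with a mean RPKM of 7.29 in WT and 0.0112 in R320*, had a fitted fold of 65.9. Among these 13, the lower mean RPKM was above 0.1 for SH3D19 (109-fold in counts and 4.55-fold in RPKM), KYNU (204-fold and 16.4-fold) and MAGED1 (76.1-fold and 9.60-fold).

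Among the smallest adjusted p-values were those of abundant transcripts that fell. AIG1 fell from 7232 ± 10.1 to 427 ± 33.1 (log2 fold change -4.08, SE 0.06, limma adjusted p = 4.36e-17). LIN28A, an RNA-binding regulator of let-7 microRNAs, fell from 4547 ± 83.4 to 149 ± 19.3 (log2 fold change -4.93). The splicing regulator CELF2 fell from 7479 ± 207 to 621 ± 52.3. COLGALT2, a collagen galactosyltransferase, fell from 7087 ± 38.7 to 1039.6 ± 3.17, and ACSM3 fell from 6097 ± 199 to 919 ± 31.1, the latter in a span shared with THUMPD1 and ERI2. Folds were smaller in RPKM for AIG1 (16.9 in counts and 10.99 in RPKM) and ACSM3 (6.63 and 3.14).

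Of 35 fixed gene lists, 31 had enough tested members for camera and 13 were called with its preset correlation of 0.01, 4 higher and 9 lower in R320*. With an estimated correlation none was called by camera, the lowest adjusted p being 0.0580, and 8 lists had an unadjusted p under 0.05. The directional fry test, which does not set a list against other genes, called 26, and its mixed form called 31. Counts of members below are over all genes tested, and the numbers adjusted over the list alone were equal except where they are given.

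Genes of cholesterol synthesis and uptake rose together. Of 21 tested members 18 were higher and 1 lower, with a median log2 fold change of 0.58 (camera adjusted p = 8.44e-10, and adjusted p = 0.0580 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose 3.11-fold, from 5350.2 ± 80.5 to 16615 ± 318. DHCR7 rose from 4761 ± 185 to 9322 ± 75.03, and INSIG1, a sterol-regulated inhibitor of SREBP processing, from 7497 ± 151 to 13198 ± 221. SC5D, an enzyme near the end of the pathway, was the member that fell, from 200.2 ± 33.6 to 118 ± 26.1, and its call was lost in the RPKM table (limma adjusted p = 0.0522, in a range of 0.000487 to 0.0522).

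The lists of MYC targets and of DNA replication were called higher in R320* cells with the preset correlation, while the mitosis list was called lower (below). MYC rose 2.22-fold, from 11247 ± 164 to 25021 ± 92.0 (log2 fold change 1.15, SE 0.03, limma adjusted p = 3.12e-14). The list of MYC targets and ribosome biogenesis genes includes MYC itself. Of its 23 tested members 18 were higher and 4 lower, with a median log2 fold change of 0.31 (camera adjusted p = 6.81e-05, and adjusted p = 0.0897 with an estimated correlation). BOP1, a factor of large ribosomal subunit assembly, rose from 5606 ± 277 to 10354 ± 297, the nucleolar proteins NOLC1 from 8547 ± 144 to 12990.1 ± 169 and NCL from 19954 ± 777 to 29155 ± 359.7. DNA replication and S phase genes were higher for 16 of 25 and lower for 2, with a median of 0.19 (camera adjusted p = 0.000836, and adjusted p = 0.138 with an estimated correlation). MCM2 rose from 5731 ± 52.6 to 7998 ± 279 and MCM6 from 6168 ± 161 to 8388 ± 68.4, both subunits of the replicative helicase, while RRM2, a ribonucleotide reductase subunit, fell from 4622 ± 158 to 2656 ± 114. TYMS, thymidylate synthase, rose from 1442 ± 8.18 to 2279 ± 44.1, with a span that overlaps ENOSF1 and in a higher window of chromosome 18. MYC and BOP1 lie in stretches of chromosome 8 whose genes were higher as a whole (below, with the positions).

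Haem synthesis and iron uptake genes were higher for 11 of 19 tested members and lower for 5, with a median log2 fold change of 0.24 (camera adjusted p = 0.00421, and adjusted p = 0.128 with an estimated correlation). FECH, the last enzyme of haem synthesis, rose from 4145 ± 55.6 to 8568 ± 147, and the mitochondrial transporters ABCB10 and SLC25A37 rose from 2401 ± 52.7 to 5964 ± 107 and from 5359.9 ± 158 to 10734 ± 22.01. The fold of ABCB10 was 2.48 in counts and 1.32 in RPKM. TFRC, the transferrin receptor, rose from 25489.7 ± 657 to 38529 ± 974. Haemoglobin genes went both ways, with 5 of 10 higher and 2 lower, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.469). The embryonic HBE1 fell from 3608 ± 191 to 2604 ± 85.4 and the adult HBD from 205 ± 10.97 to 51.0 ± 10.3. The fetal HBG1 was 13338 ± 589 and 20932 ± 4419.7 and HBA2 was 1116 ± 79.5 and 2076 ± 466, values that are uncertain because HBG1 and HBG2, and HBA1 and HBA2, are near-identical copies. Erythroid regulators and membrane proteins were higher for 15 of 28 and lower for 7, or 15 and 8 adjusted over the list alone (camera adjusted p = 0.170). Among them SPTB, the erythrocyte spectrin beta chain, rose from 7134 ± 309 to 12554 ± 347 and CA2, a carbonic anhydrase, from 178 ± 35.5 to 703 ± 61.5. SLC4A1, the band 3 anion exchanger, fell from 703 ± 21.3 to 212 ± 18.0, and the erythroid and megakaryocytic factor NFE2, within the lowered segment of chromosome 12, from 11903 ± 137 to 5972 ± 268.

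Megakaryocyte and platelet genes fell in R320* cells. Of 18 tested members 12 were lower and 3 higher, with a median log2 fold change of -1.31 (camera adjusted p = 9.68e-05, and adjusted p = 0.0897 with an estimated correlation). TUBB1, the platelet-specific beta tubulin, fell from 1664 ± 126 to 292 ± 23.8 (log2 fold change -2.51, SE 0.08, limma adjusted p = 4.51e-13). ITGA2B, the integrin alpha chain of the platelet fibrinogen receptor, fell from 1343 ± 15.6 to 428 ± 58.6. RAB27B, a GTPase of granule secretion, fell from 738 ± 10.6 to 78.2 ± 8.55, and the angiopoietin gene ANGPT1 from 2196 ± 127 to 946 ± 46.4. Granulocyte and monocyte genes were lower for 7 of 10 and higher for 1, with a median of -0.59 (camera adjusted p = 0.0359, and adjusted p = 0.207 with an estimated correlation). FCGR2A, an Fc receptor, fell from 2309 ± 27.3 to 451 ± 22.1, CD68 from 359 ± 18.2 to 196 ± 36.3 and CEBPB from 980.1 ± 73.5 to 707 ± 37.1. The granulocyte and monocyte list lost its call without WT replicate 1 (camera adjusted p = 0.0657), within a range of 0.00976 to 0.207 over its alternatives.

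Haematopoietic stem and progenitor genes were higher for 6 of 10 and lower for 3 (camera adjusted p = 0.154). KIT, the stem cell factor receptor, rose 5.19-fold, from 183 ± 25.4 to 956 ± 127, and MLLT3 rose from 46.2 ± 11.9 to 165 ± 26.3. HHEX rose from 2889 ± 150.5 to 3857 ± 28.0 and IGF2BP2 from 2434 ± 98.1 to 3227 ± 82.9. Genes named in the literature as RUNX1-regulated were split, with 6 of 18 higher and 6 lower, or 7 and 6 adjusted over the list alone (camera adjusted p = 0.956). Their median log2 fold change was 0.17 and their mean -0.18, and the direction of the test was higher. HPGD, which degrades prostaglandins, rose 6.67-fold (log2 fold change 2.74, SE 0.07). The D-type cyclin CCND3 fell from 12844 ± 235 to 4937 ± 187, and the cell cycle inhibitor CDKN1A fell from 415 ± 38.0 to 57.4 ± 15.5.

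Interferon-response genes were lower in R320* cells. Of 16 tested members 11 were lower and 1 higher, with a median log2 fold change of -1.12 (camera adjusted p = 0.000357, and adjusted p = 0.128 with an estimated correlation). The median was also -1.12 with the 2 members at 0 in R320* set to their bound. OAS3, an antiviral oligoadenylate synthase, fell from 491 ± 36.5 to 19.6 ± 13.7, and STAT2, which carries the type I interferon signal, from 2107 ± 83.0 to 943 ± 27.2. The fold of OAS3 was 27.3 in counts and 9.75 in RPKM. IFITM1 fell from 5634 ± 75.2 to 3187 ± 85.6 and the transcription factor IRF1 from 511 ± 10.7 to 233 ± 5.90. OAS3, STAT2 and IRF1 lie in the lowered segments of chromosomes 12 and 5, and the median of the members outside the segments was -0.89.

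Apoptosis regulators fell for 10 of 16 tested members and rose for 0, with a median log2 fold change of -0.41 (camera adjusted p = 0.000836, and adjusted p = 0.121 with an estimated correlation). Members that fell included both inhibitors and promoters of cell death. The anti-apoptotic BCL2 fell from 671 ± 93.8 to 166 ± 17.6, BCL2L1 from 6948 ± 132 to 3709 ± 83.1 and CFLAR from 6597 ± 241 to 3531 ± 82.4, and the pro-apoptotic BCL2L11 from 2287 ± 56.0 to 1349 ± 54.9. Cell cycle inhibitors and p53 targets were lower for 8 of 16 and higher for 2, with a median of -0.42 (camera adjusted p = 0.0467, and adjusted p = 0.395 with an estimated correlation). SESN2 fell from 4674 ± 60.0 to 2518 ± 60.9 and CDKN2C from 1999 ± 8.36 to 1103 ± 77.5, while the death receptor gene TNFRSF10B rose from 878 ± 49.9 to 1507 ± 96.7. Mitosis genes were lower for 13 of 24 and higher for 2, with a median of -0.13 (camera adjusted p = 0.0467, and adjusted p = 0.535 with an estimated correlation). TOP2A fell from 17807 ± 433 to 12966 ± 518 and PTTG1, securin, from 4569 ± 131 to 2403 ± 84.3, while the checkpoint kinase BUB1 rose from 8579 ± 156 to 13599 ± 93.9. The mitosis list kept its call in 10 of 19 alternatives, and lost it without WT replicate 1 (camera adjusted p = 0.0657), WT replicate 2 (0.0550) or R320* replicate 3 (0.101), in a range of 0.0108 to 0.535, and without the genes of the lowered segments (0.0855), which hold PTTG1. It was also lost with at least 100 counts (0.0755), upper-quartile scaling (0.0559), no intensity trend (0.0576) and in RPKM (0.108). The inhibitor and p53 list also kept its call in 10 of 19, and lost it without WT replicate 1 (camera adjusted p = 0.0680), WT replicate 3 (0.0675), R320* replicate 1 (0.0631) or R320* replicate 2 (0.0510), in a range of 0.0186 to 0.395, and further with at least 100 counts (0.0836), in RPKM (0.0621) and with segment medians subtracted (0.0802).

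Genes of the unfolded protein and integrated stress response were lower for 12 of 19 tested members and higher for 4, or 13 and 5 adjusted over the list alone, with a median log2 fold change of -0.33 (camera adjusted p = 0.00258, and adjusted p = 0.128 with an estimated correlation). TRIB3, a pseudokinase induced by the stress response, fell from 5068 ± 181 to 1942 ± 54.5. PSAT1, of serine synthesis, fell from 9024 ± 313 to 5091 ± 151, and SHMT2, of mitochondrial one-carbon metabolism, from 9757 ± 136 to 5859 ± 199, the latter within the lowered segment of chromosome 12. Nuclear-encoded oxidative phosphorylation genes were lower for 13 of 22 and higher for 1, with a median of -0.15 (camera adjusted p = 0.00421, and adjusted p = 0.281 with an estimated correlation). ATP5F1B, the ATP synthase beta subunit, fell from 48890.0 ± 516 to 26162 ± 339, also within that segment, and COX4I1 from 12254 ± 252 to 9532 ± 349. Replication-dependent histones were lower for 9 of 12 and higher for 0, with a median of -0.76 (camera adjusted p = 0.000529, and adjusted p = 0.269 with an estimated correlation). H1-2 fell from 7769.9 ± 280.1 to 3649.8 ± 246 and H2BC12 from 12141 ± 55.9 to 7766 ± 288, values that are uncertain because histone genes share sequence. The oxidative phosphorylation list lost its call in the RPKM table (camera adjusted p = 0.0515), in a range of 0.000718 to 0.281 over its alternatives.

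**Figure D2:**
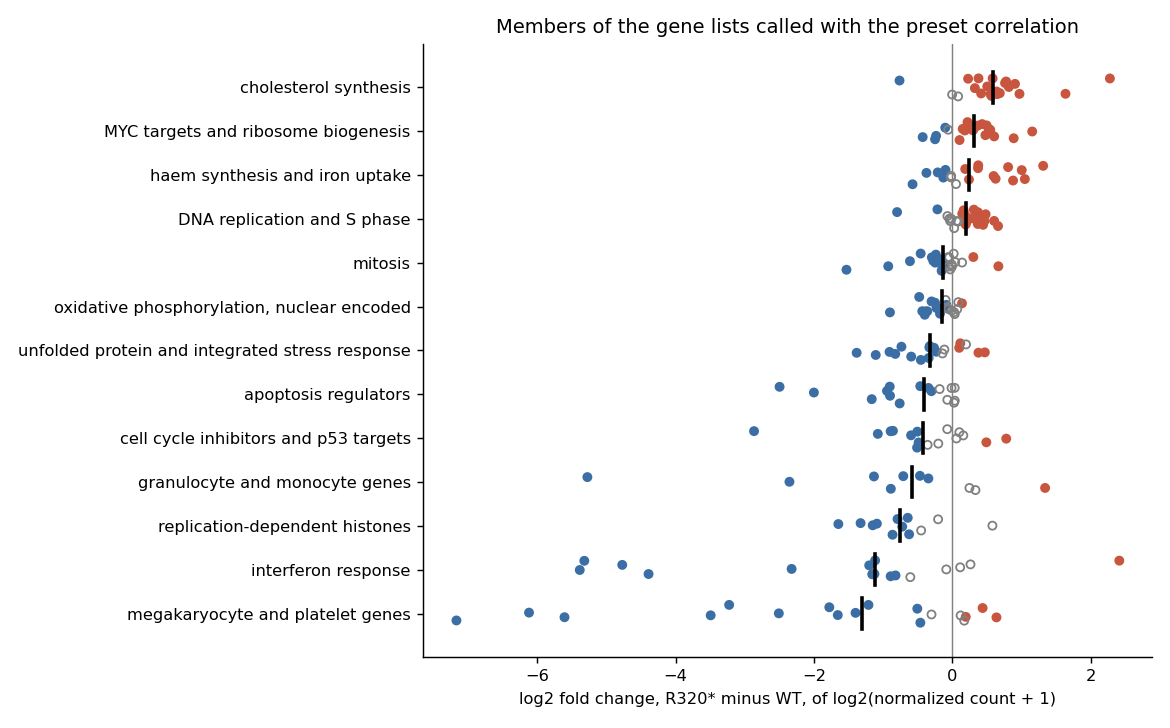
Log2 fold changes (R320* minus WT, horizontal axis) of the tested members of the 13 gene lists called with the preset correlation, 1 point per gene, filled where the gene passed the limma test and open where it did not, with a bar at each list's median. Medians ran from -1.31 for megakaryocyte and platelet genes to 0.58 for cholesterol synthesis.

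Signalling and metabolic lists that camera did not call held strongly changed members in both directions. Of 22 tyrosine kinase and cytokine signalling genes 9 were higher and 11 lower, or 9 and 12 adjusted over the list alone (camera adjusted p = 0.469). FYN, a Src-family kinase, fell from 1384 ± 48.6 to 95.6 ± 21.4, and the kinase PIM2 fell from 6496 ± 241 to 2153 ± 39.9. The cytokine signalling inhibitor SOCS3 rose from 373 ± 26.8 to 1136 ± 55.7, while SOCS2, within the lowered segment of chromosome 12, fell from 7980.1 ± 114 to 2887 ± 16.8. Of 23 glycolysis and hypoxia genes 13 were higher and 7 lower, or 13 and 8 adjusted over the list alone (camera adjusted p = 0.154), with the glucose transporter SLC2A1 rising from 4369.9 ± 101 to 8480.4 ± 137 and SLC2A3 falling from 11273 ± 403 to 5249 ± 54.9. Integrins and cell adhesion genes were lower for 7 of 15 and higher for 2, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0642). ITGB5 fell from 1182 ± 74.8 to 80.1 ± 21.6 and CD44, the hyaluronan receptor, from 408 ± 23.4 to 46.0 ± 15.3. The adhesion list was called lower without R320* replicate 1 (camera adjusted p = 0.0435), with no filter (0.0312) and in RPKM (0.0148), in a range of 0.0148 to 0.248 over its alternatives.

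Immediate early and AP-1 genes were lower for 8 of 19 and higher for 4 (camera adjusted p = 0.154), with SPRY2, an inhibitor of growth factor signalling, falling from 334 ± 30.6 to 50.6 ± 21.6. TGF-beta response genes were lower for 7 of 13 and higher for 3, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.160), with ID3 falling from 307 ± 36.4 to 81.0 ± 15.0 and TGFBR3 rising from 849 ± 22.7 to 1379 ± 70.6. TNF and NF-kB targets were higher for 4 of 12 and lower for 5 (camera adjusted p = 0.925). The chemokine CXCL3 fell from 338 ± 53.1 to 46.8 ± 5.604 and CXCL2 from 203 ± 14.1 to 30.9 ± 10.1, while IL6 rose from 66.2 ± 6.67 to 194 ± 17.4. Heat shock proteins were higher for 7 of 11 and lower for 3 (camera adjusted p = 0.128, but 0.0163 in RPKM, in a range of 0.0163 to 0.361), among them HSP90AB1, which rose from 101538 ± 1312 to 122114 ± 826. Loop extrusion and enhancer-promoter factors were higher for 6 of 21 and lower for 1 (camera adjusted p = 0.154), and 14 members did not pass. LDB1, an adaptor of enhancer-promoter contacts, rose from 11539.6 ± 148 to 14074 ± 619.9 and the cohesin subunit RAD21 from 9285 ± 316 to 11313 ± 536. Chromatin regulators mutated in myeloid leukaemia were lower for 11 of 21 and higher for 4 (camera adjusted p = 0.1001, but 0.0476 with no filter and 0.0457 with quantile normalization, in a range of 0.0457 to 0.364). IDH2 fell from 2793 ± 104 to 1056 ± 18.5 and EZH2 from 5752 ± 143 to 3918 ± 97.3, while DNMT3A rose from 1236 ± 41.6 to 1965 ± 113.

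Markers of other cell types were not called as groups by camera, while the directional fry test called T and NK, fibroblast and epithelial markers. T and NK lymphocyte markers were lower for 2 of 6 tested (camera adjusted p = 0.242), with PRF1 falling from 313 ± 26.1 to 34.9 ± 11.5. Endothelial markers were higher for 2 of 6 and lower for 3 (camera adjusted p = 0.925), with a median of -0.26, a mean of -0.37 and a test in the higher direction. Fibroblast and mesenchymal markers were higher for 3 of 11 and lower for 4 (camera adjusted p = 0.353), with a median of 0.10, a mean of -0.32 and a test in the lower direction. SPARC, within the lowered segment of chromosome 5, fell from 2504 ± 77.0 to 168 ± 20.8, and LGALS1 from 4418 ± 154 to 1484 ± 107, while VIM rose from 5172 ± 142 to 7531 ± 357. Epithelial markers were higher for 3 of 9 and lower for 3 (camera adjusted p = 0.925), with a median of -0.25, a mean of 0.25 and a test in the higher direction. KRT19 rose from 1923 ± 56.0 to 6041 ± 191 and EPCAM from 2326 ± 29.3 to 5149.7 ± 146. Lists with too few tested members for camera were B lymphocyte markers (1 of 3 lower), mast cell, basophil and eosinophil markers (2 of 4 higher and 1 lower) and antigen presentation genes (1 of 4 higher and 1 lower). Antigen presentation genes had a median of -0.14 and a mean of 0.22. None of the transcripts of the mitochondrial genome on the list was matched in the table.

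Genes seen on 1 side only were those below 1 normalized count in every library of a genotype and at least 20 in every library of the other. There were 24, of which 6 were seen in R320* and 18 in WT. The 6 seen in R320* were MAGEB16, CFAP47, CT83, MS4A4A, SH2D4A and XIRP2, and each had no read in any WT library. Among the 18 seen in WT, 2 were chosen after their values were seen. PIEZO2, a mechanosensitive channel, had a mean of 64.5 ± 8.52 against 0 (at least 21.6-fold lower in R320*), and IFIT1, an interferon-induced gene, 39.4 ± 7.42 (at least 13.2-fold). Bounds cover counting error only. LYZ, also among the 18, was at 48.0 ± 7.66 in WT and 0.327 ± 0.566 in R320* in counts. In the RPKM table it was seen in both genotypes, at 6.32 ± 0.661 and 4.61 ± 0.750 (limma adjusted p = 0.0616), so its absence from R320* is uncertain.

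The authors' deposited RPKM table, made from the same libraries, gave the same direction for most genes that both tables called. Of its 17769 tested genes 5675 (31.9%) changed, with 2692 higher and 2983 lower in R320* (limma adjusted p below 0.05), and 1366 of them had an absolute log2 fold change of at least 1. Of the 12412 genes tested in each of them, 4488 were called in both, 4479 of these in the same direction. There were 2110 genes higher in both and 2369 lower in both, and since both tables come from the same 6 libraries, this overlap is not independent evidence. Log2 fold changes correlated with r = 0.914 across genes, which are not independent replicates. The count table alone called 2562 of these genes and the RPKM table alone 387. The 9 genes called in opposite directions were CALB1, ABCF1, DNAJA3, ERVW-1, RPS10, RPL36A, TNRC6B, SEPTIN9 and SPCS3. MYC rose from 145 ± 1.15 to 309.6 ± 9.43, HMGCS1 from 79.98 ± 1.93 to 262 ± 9.33, and TUBB1 fell from 12.6 ± 0.980 to 1.90 ± 0.187 in RPKM. Long noncoding RNAs made up 3759 of the genes tested in RPKM, with 272 higher and 379 lower.

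Lowered genes were concentrated on parts of chromosomes 5 and 12. On chromosome 12 the 563 tested genes from 42312086 to 133214832 (GRCh38) had a median log2 fold change of -0.60, with 438 lower and 18 higher, while the other 200 genes of the chromosome had a median of -0.06. On chromosome 5 the 387 tested genes from 94150851 to 181328195 had a median of -0.38, with 257 lower and 25 higher, against 0.05 for the other 250. The strongest calls within these segments were SPARC, RNF130 (from 2617 ± 17.4 to 908 ± 23.4) and PAM, which rose (log2 fold change 1.82), on chromosome 5, and SOCS2, RAP1B (from 5960.4 ± 173 to 2433 ± 68.2) and ATP5F1B on chromosome 12. Medians in the RPKM table were -0.54 and -0.34 for the same segments. On chromosome 8, the window from 125024260 to 143618048 had a median of 0.47 and the next, from 143636019 to 145056030, of 0.41, and they hold MYC and BOP1. On chromosome 6, the window from 26055740 to 27958182, which holds most of the tested histone genes, had a median of -0.44. Other windows past the test held KYNU on chromosome 2, CXCL2 and CXCL3 on chromosome 4, SC5D on chromosome 11 (lower), SLC2A1 on chromosome 1, RAD21 on chromosome 8, SOCS3 on chromosome 17, HBG1 on chromosome 11 and HBA2 on chromosome 16 (higher).

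In a permutation test that shuffled fold changes over the 14141 positioned genes, 10 of 23 chromosomes and 43 of 283 windows of 50 neighbouring genes passed, 16 windows higher and 27 lower, with 15.4% of the positioned genes. The permutation p was 1e-05 for chromosomes 5, 6, 8, 12, 16 and 19, the smallest the 100000 permutations can give. Chromosome medians were -0.49 for chromosome 12, -0.24 for chromosome 5 and 0.12 for chromosome 8. They were smaller for chromosomes 6 (-0.080), 16 (0.096) and 19 (0.099). Segments were defined as 3 or more neighbouring windows past the test with a median of at least 0.25 in size, a rule set after the data were seen. Within the segments 738 of 950 genes (77.7%) were called, and outside them 6892 of 13191 (52.2%). The shuffle treats genes as independent, which neighbours are not. The spans of CEBPB, TNFRSF10B, ATP5F1B and LDB1 overlap those of other genes in the table, and the sources used here do not say whether counting used strand, so their reads are uncertain as well.

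**Figure D3:**
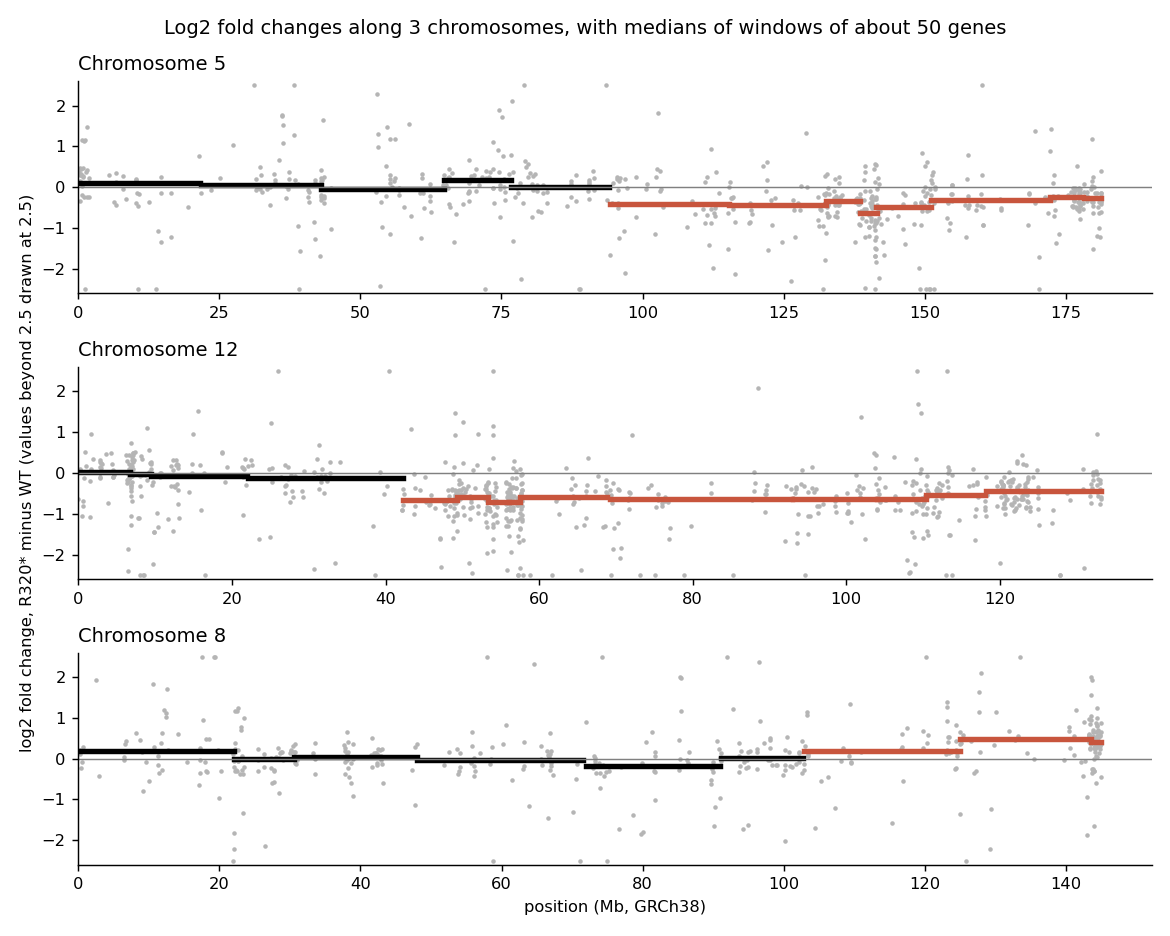
Log2 fold change (R320* minus WT) of the tested genes (grey points, values beyond 2.5 drawn at 2.5) by position in Mb on chromosomes 5, 12 and 8, with the median of each window of 50 neighbouring genes as a bar, coloured where it passed the permutation test. Bars lie below 0 along the distal part of chromosome 5 (median -0.38) and most of chromosome 12 (median -0.60), and above 0 at the end of chromosome 8.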

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

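The fits without the genes of the lowered segments, the fits with segment medians subtracted, and the edgeR and DESeq2 fits of single genes were chosen after the data were seen. RUNX1 stayed higher and past the test in all alternatives, with log2 fold changes of 0.80 to 0.84 when each library was left out in turn. The number of changed genes (7685) was 5675 in the RPKM table, and within the count table it ran from 6692 without the intensity trend to 7854 with the replicate block, and from 6931 to 7314 with a library left out. It was 7660 with edgeR, 7340 with DESeq2, 6894 without the segment genes and 7438 with segment medians subtracted. The balance of higher and lower genes (3771 and 3914) turned to 4194 and 3551 with quantile normalization, 3956 and 3779 with upper-quartile scaling, 3700 and 3194 without the segment genes and 3981 and 3457 with segment medians subtracted. With an absolute log2 fold change of at least 1 it was 1626 (630 higher and 996 lower), by construction. Genes seen on 1 side only (24) were 42 with a bound of 3 in the lower genotype and 8 with a bound of 50 in the higher. The number of lists called (13) ran from 10 to 15, except that it was 0 with an estimated correlation in camera, with 8 at an unadjusted p under 0.05. Genes called were 6792 with at least 100 counts in 3 libraries and 7793 without a filter, and depth itself was not varied. Changed genes in RPKM (5675) ran from 4497 to 5070 with a library left out. Camera offers no robust variance option, so that alternative was not run for lists.

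Of 177 named genes called, 165 kept call and direction in all alternatives in which they were tested, and 11 lost the call in at least 1. Not every gene was tested in every alternative. Most were named for a small adjusted p or a large change, so this share does not carry over to other genes. RUNX2, EPX and NLRC5 lost it without WT replicate 2, EPX and IGLL1 without WT replicate 1, EPX without WT replicate 3, RUNX2, EPX and IGLL1 without R320* replicate 2, and EPX and NLRC5 without R320* replicate 3. EPX also lost it with no filter, with quantile normalization, with edgeR and the replicate block and with DESeq2 (Wald adjusted p = 0.0931), in all in 9 of its 21 alternatives. LYZ, PHGDH, GATA2, TIE1, SC5D and CBFB lost it in RPKM, CBFB also without the trend, and KRT18 with segment medians subtracted. EGR1, in the segment of chromosome 5, went from -0.26 to 0.12 with the segment median subtracted.

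The following turned direction without having been called, and the cause was not tested. The camera adjusted p of the RUNX1-regulated list (0.956) was 0.819 with at least 100 counts, 0.992 with quantile normalization, 0.495 in RPKM, 0.965 with segment medians subtracted, and 0.931 to 0.990 over the fits with a library left out, of which it turned without R320* replicate 1 and without R320* replicate 2. The epithelial list (0.925) had 0.915 with at least 100 counts, 0.999 without the trend and 0.880 in RPKM. It ranged from 0.832 to 0.958 with a library left out and turned in 1 of these fits, without R320* replicate 3 (0.956). The endothelial list (0.925) had 0.799 without the trend, 0.961 without the segment genes and 0.968 with their medians subtracted. The log2 fold change of CD3G (-0.06) was 0.0405 with quantile normalization and -0.15 to 0.0750 with a library left out, that of PRG2 (0.16) -0.0552 to 0.38, and that of TAP2 (-0.52) -1.23 to 0.14. Of these fits CD3G and PRG2 turned without WT replicate 1 and TAP2 without R320* replicate 2. CIITA (0.05) had -0.38 in RPKM, -0.0194 and -0.0167 with edgeR, -0.0180 with DESeq2 and -0.25 to 0.37 with a library left out, turning without WT replicate 3 and without R320* replicate 3.

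The replicate numbers did not pair the libraries. Deviations of libraries with the same number correlated with r of 0.0165, -0.000862 and 0.0122 over 10965 genes, those with different numbers with -0.0438 to 0.0294, and 1 library correlated best with its own number. With the replicate block 7854 genes (3874 higher and 3980 lower), 12 lists and 4865 genes in RPKM were called, where the inhibitor and p53 list was not (camera adjusted p = 0.0516, in a range of 0.0186 to 0.395).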

Other observations

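The tests of the R320* protein within segments, of RNA without a poly(A) tail, of S phase, and both tests of the megakaryocyte list were chosen after the results were seen, as were the families of genes by name and the genes named in the next paragraph.

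Strongly changed genes often lay side by side, outside the segments of chromosomes 5 and 12. IL18R1, the partner subunit of IL18RAP, fell from 352 ± 3.84 to 11.7 ± 0.242 beside it on chromosome 2. The epidermal growth factor family ligands EREG and AREG, neighbours on chromosome 4, fell, EREG from 26.2 ± 7.18 to 0 in each R320* library and AREG from 573 ± 25.2 to 24.6 ± 6.79, near the chemokine genes CXCL1, CXCL2 and CXCL3. SOX13 and ETNK2, neighbours on chromosome 1, fell, SOX13 from 177 ± 22.1 to 11.7 ± 3.07 and ETNK2 from 109 ± 12.8 to 12.7 ± 1.92. HDAC9, a histone deacetylase, fell from 1033 ± 87.3 to 54.1 ± 14.8 with its neighbours PRPS1L1 and TWIST1 on chromosome 7. CCND1, the cyclin D1 gene, fell from 1645 ± 18.4 to 55.3 ± 14.2 with its neighbour MYEOV. GPM6A and WDR17, next to HPGD on chromosome 4, rose from 1.35 ± 2.34 to 83.0 ± 9.98 and from 1.70 ± 0.613 to 38.5 ± 13.1, and the cytokine genes LIF and OSM on chromosome 22 rose from 10.9 ± 3.37 to 119 ± 7.89 and from 29.5 ± 3.73 to 129 ± 22.8.

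Families of genes that share a name stem were also tested, 129 of them with at least 12 tested members, after the fixed lists. Genes named COX, mostly subunits and assembly factors of cytochrome c oxidase, were lower for 16 of 25 and higher for 2 (median log2 fold change -0.32, camera adjusted p = 0.0155). Genes named MCM, among them subunits of the replicative helicase, were higher for 9 of 12 and lower for 1 (median 0.31, camera adjusted p = 0.0387). Each had an adjusted p = 0.995 with an estimated correlation. Among families not called, PCDHB protocadherins on chromosome 5 had a median of -0.94, with 8 of 13 lower. They lie within the lowered segment and resemble each other in sequence, so their counts are uncertain.

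A hypothesis fixed before its test was that changes take in stretches of chromosome. Among 540 genes outside the segments that changed by at least 2 on the log2 scale, 61 adjacent pairs that do not overlap moved in the same direction, 46 lower and 15 higher, and 14 moved in opposite directions. Shuffles gave a median of 10 such pairs, between 4 and 17 in the central 95% and at most 23 (permutation p = 0.0001, the smallest that 10000 shuffles can give). Part of the changes may therefore involve stretches of chromosome, but neighbours that are members of a gene family, such as the IFIT and CXCL genes, share regulation in any case, and the shuffles did not account for that.

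The lowered segments of chromosomes 5 and 12 had medians of -0.38 and -0.60. Removing the trend on GC content and transcript length left medians of -0.35 and -0.58 (smallest size 0.352), which argues against that bias as the whole cause. Genes of low, middle and high expression shifted by similar amounts, with at most 0.119 between the tertile medians of a segment, so a different number of DNA copies of these segments in the WT and R320* cultures may account for the shift. The medians lie near those of 3 copies against 4 (-0.42) and 2 against 3 (-0.58), but DNA was not analysed here, and this explanation was found and tested on the same data. The higher windows at the end of chromosome 8 (medians 0.47 and 0.41) fell short of the rule for segments, so DNA copies there were not tested. The genes they hold, MYC and BOP1 among them, stayed in the fits without the segment genes. An action of the R320* protein on genes within the lowered segments cannot be told apart from a different number of DNA copies. Fold changes were as widely spread there as elsewhere (smallest ratio of interquartile ranges 1.01, between the bounds set for either outcome). A shift that moves all genes of a segment alike leaves their spread as it is, so this ratio does not decide between them.

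Replication-dependent histones fell, with a median of -0.76. Less carry-over of RNA without a poly(A) tail was looked for in 128 other such RNAs. They had a median of 0.23 (95% interval 0.17 to 0.34), with 15 higher and 0 lower by limma. Most were small nucleolar RNAs (47 named SNORA and 77 named SNORD). The most abundant had lower means in R320* without a call, RN7SL1 (10286 to 7575, limma adjusted p = 0.905) and RN7SL2 (16031 to 11712, limma adjusted p = 0.529). Since poly(A) selection is not stated either, carry-over stays open. Fewer cells in S phase were looked for in the replication list, in which 16 of 25 members were higher and 2 lower. Its median was 0.19 (camera adjusted p = 0.000836, and adjusted p = 0.138 with an estimated correlation). That direction was known when the test was chosen, and the mitosis list was lower for 13 of 24 and higher for 2. Transcript levels do not count cells in S phase, so this explanation stays open. A regional shift was looked for in 18 other genes between the histones on chromosome 6, from 26.03 to 27.87 Mb. They had a median of -0.26, with 7 lower and 4 higher. The largest falls were those of the related genes BTN3A1 (-2.15), BTN3A3 (-1.46) and BTN3A2 (-0.99). The tested BTN2A genes were below 0 too, so the median rests in part on 1 gene family. Other called genes went both ways, with ZNF322, PRSS16 and ZNF204P lower and HCG11, ABT1, GUSBP2 and ZNF391 higher. The median lies between the bounds set for either outcome, so a regional shift and an effect on histones alone cannot be told apart.

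Megakaryocyte and platelet genes fell, with a median of -1.31. All 18 tested members lie outside the lowered segments (median outside them -1.31). This argues against a direct effect of DNA copies of these segments on the members. An indirect effect through a gene within the segments, such as NFE2, was not tested. A share of mature megakaryocytes in the WT cultures would bring their abundant transcripts, but PF4, CLEC1B and TREML1 had 0 in every library, and the highest of 6 platelet transcripts in a WT library (PPBP, 17.9) was 0.0302 of the median fall of 595 counts among the 12 members that fell, which argues against such a share as the cause. A bound used first, a WT mean of 10 counts, which PPBP passed with 12.8 ± 7.49, took no account of the size of the fall and was replaced after the values were seen. An effect of R320*, other differences between the cultures and a share of less mature cells were not tested and stay open.

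The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split called 7685 genes with limma, 5675 in the RPKM table and 13 lists with camera, and the highest of the other splits were 0, 5 and 6, so 1 of 10 splits gave a result as large in each case. Each of the other splits mixes the genotypes within its groups, which adds the genotype difference to the spread. Few called genes there follow from the design, so these splits do not show what chance alone would give.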
